A study of Mus musculus with 30 samples.

How the data were processed

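Liver RNA of 30 mice was measured on Affymetrix Clariom D mouse (MTA-1_0) arrays, 1 array per mouse. Per the labels, RNA came from snap-frozen liver and was purified with the miRNeasy mini kit, and biotinylated cRNA was made from 1 ug of RNA. Strain, sex and the time of day of sampling are not given in the sources used here. The study design also names DNA methylation at selected CpG sites, which was not examined here.

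The deposited values are log2 signals per transcript cluster, made by the authors with RMA. Per the submitters' processing notes, Transcriptome Analysis Console 4.0.2.15 and RMA were used. Their order and settings are not given in the sources used here. The log base is not stated and was taken as log2, the base that RMA returns. Values ran from 2.03 to 19.66, and 632 clusters had a mean above 16, the log2 limit of a 16-bit scan. This points to a rescaling that the notes do not name, which was not tested. No value was missing. The annotation is the manufacturer's NetAffx build 36 for mm10, per the file header. Its 6732 control probe sets are not among the values.

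Of 65956 transcript clusters 36587 carried exactly 1 gene symbol and were used. The 3574 with several symbols and the 25795 with none were left out. For the 282 genes with more than 1 cluster, that with the highest mean over all arrays was kept, which gave 36248 genes, and no filter on dim genes was applied. Symbols of 1022 genes were updated through their Entrez number. Groups followed the diet and the weeks of feeding in the labels. The label called age holds the weeks of feeding. The numbers in the sample titles were read as mouse numbers, and since each occurs once, no pairs were formed.

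Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 30 arrays, with 26 residual and 4.03 prior degrees of freedom. In all, 5 contrasts were tested with its moderated, two-sided test: diet at 1 week, diet at 12 weeks, the difference of both diet effects, and 12 against 1 week within each diet. The diet contrasts share no arrays with each other. Adjusted p values are Benjamini-Hochberg values over the genes of a contrast, with a threshold of 0.05. A set of 34 gene lists, 791 memberships of which 755 were measured, was tested with camera at a preset correlation of 0.01 and a minimum of 5 members. Beside it stand camera with an estimated correlation and fry. The packages were the R package data.table at version 1.17.8 and pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 in Python 3.11.15.

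Comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named are, for each diet contrast, the 8 genes with the largest rise and the 8 with the largest fall among called genes of at least median signal, and 5 and 5 for each other contrast, without predicted and clone-named genes. A few genes that this rule names are not reported here. Up to 4 members with the smallest p were named for each list described. Which lists are described in detail was chosen after the values were seen. Of the list members 36 were not tested, 35 of them because their cluster carries several names, among them Cyp4a10, Srebf1 and Ass1.

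The array number limits the precision. The steps were tested on simulated data with 200 planted genes: of those changed by 0.5 log2 units, between 50.7% and 74.6% were recovered in the 5 contrasts, of those changed by 1 unit between 85.1% and 100%, and between 3.7% and 4.9% of the calls were unplanted genes. A list planted with a shift of 1 was found in each of the 5 contrasts, with 0 of 33 others called. The simulated genes varied independently of each other, unlike those of the measured lists, so these rates need not hold for the measured data. Splits of the measured arrays, described below, called a median of 8 to 13 lists.

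Alternatives were a filter at the median signal of 5.69, all clusters, the mean of clusters, limma with trend and robust options, array weights, a repeated quantile normalization, centred array medians, a fold change of at least 1.5 in addition, each mouse left out in turn, only the groups compared (weights by group for the difference of both diet effects) and Spearman's correlation. A further 3 were added after the data were seen: without mice 59 and 60, without mice 41 and 43, and with a clock gene score per array as a covariate. The score is the mean of 6 standardised genes (Dbp, Tef, Per1, Per2, Per3, Ciart) minus that of 3 (Arntl, Npas2, Clock), and since diet itself can move these genes, the covariate can remove diet effects. Scores per array of this and 4 lists were compared by two-sided exact permutation tests. Splits of the arrays were drawn 100 times. Gene ontology terms of 10 to 500 genes were tested with Fisher's exact test against the 20483 tested genes with a term, a step also chosen after the data were seen.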

Results

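Gene expression was measured in the livers of 30 mice with 1 Affymetrix Clariom D mouse array per mouse. Animals had received a chow diet (standard rodent feed) or a high-fat diet for 1 or 12 weeks. The groups were chow for 1 week (n = 7), high-fat diet for 1 week (n = 8), chow for 12 weeks (n = 7) and high-fat diet for 12 weeks (n = 8). Each array was labelled with a mouse number that occurred on no other array, so the groups were compared as independent animals, and their number limits the precision. Cage, order of sampling and any array batch within a group were not modelled. If mice of a group depended on each other through these, the p values would be too small. Array medians lay between 5.24 and 5.47 log2 units, and the median over genes of the mean signal was 5.69. The signals of 36248 genes were compared, of which 19859 were annotated as protein coding. A group mean near these medians lies near the array background, so the size of a change from or to it is a lower bound. This applies to Cyp2b9, Cyp2b13, Moxd1, Adgrf1, Scara5, Mogat1, Mmp12, Gpnmb, Dhrs9, Fabp5, Mx1, Noct and Bhlhe41 below. The first principal component held 23.5% of the variance and the second 14.6%. Every array of mice fed the high-fat diet for 12 weeks lay above the high-fat arrays of 1 week on the first component, with scores from 12.2 to 34.41 and from -31.74 to -7.83. Levels and changes are given as log2 signal with the standard deviation (SD) or standard error (SE). Beside a gene, the number of mice counts those of the group named first that lay on the stated side of the mean of the other group.

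The comparison of both diets after 1 week asked which liver transcripts had responded early. Genes of lipid synthesis were lower on the high-fat diet. Scd1 (Entrez 20249, mm10 chromosome 19, 44394450 to 44407709), the desaturase that makes oleic acid from stearic acid, lay at 18.20 ± 0.17 on chow (SD, n = 7) and at 15.34 ± 0.96 on the high-fat diet (SD, n = 8). That was 7.25-fold lower (log2 fold change -2.86, SE 0.33, adjusted p = 1.77e-06, lower in 8 of 8 mice). Me1, which supplies NADPH for lipid synthesis, fell by 2.74 (SE 0.26, adjusted p = 4.63e-08, 8 of 8 mice). Acss2, which makes acetyl-CoA from acetate, fell by 1.96 (SE 0.26, adjusted p = 1.94e-05). Elovl6, an elongase of saturated fatty acids, fell by 1.60 (SE 0.24, adjusted p = 0.000100). Of 26 measured fatty acid synthesis genes 13 fell, none rose and 13 did not pass, and 20 fell when adjusted over the list alone (median -0.69, camera adjusted p = 8.80e-28, 0.00384 with an estimated correlation). Without mice 59 and 60, described below, 10 fell.

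Cholesterol synthesis genes moved the same way. Of 19 measured members 14 fell and 5 did not pass, and all 19 fell when adjusted over the list alone (median -0.81, camera adjusted p = 8.80e-28, 0.00865 with an estimated correlation). The members with the smallest p were Sc5d (log2 fold change -0.58, SE 0.09, adjusted p = 0.000249, 8 of 8 mice), Pmvk (-1.61, SE 0.27, adjusted p = 0.000399, 8 of 8), Acat2 (-0.46, SE 0.08, adjusted p = 0.000585, 8 of 8) and Hmgcs1 (-1.33, SE 0.25, adjusted p = 0.00219, 7 of 8). Hmgcs1 makes the precursor that HMG-CoA reductase converts to mevalonate. The number that fell was 18 without mice 59 and 60, and with a clock gene score of each array as a covariate it was 10.

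Detoxification genes were lower as well. Cyp3a11 (Entrez 13112, chromosome 5, 145854426 to 145879964), a major drug-oxidizing cytochrome P450, fell from 18.22 ± 0.33 (n = 7) to 15.13 ± 0.48 (n = 8), which was 8.53-fold lower (log2 fold change -3.09, SE 0.26, adjusted p = 6.02e-09, 8 of 8 mice). Cyp2c55 fell by 3.13 (SE 0.27, adjusted p = 9.15e-09) and Cyp3a25 fell by 2.21 (SE 0.24, adjusted p = 8.44e-07), each in 8 of 8 mice. In the xenobiotic metabolism list 16 of 32 genes fell and 16 did not pass, with the same count of 16 adjusted over the list alone (median -0.52, camera adjusted p = 8.80e-28, 0.000711 with an estimated correlation), and 11 fell without mice 59 and 60. Among glutathione and NRF2 target genes, which encode antioxidant and conjugating enzymes, 15 of 26 fell, none rose and 11 did not pass. Adjusted over the list alone, 18 fell and 1 rose (median -0.74, camera adjusted p = 1.62e-31, 0.000283 with an estimated correlation). Its members with the smallest p were the glutathione transferases Gstm1 (-1.67, SE 0.16, adjusted p = 6.67e-08), Gstm4 (-1.76, SE 0.17, adjusted p = 8.36e-08), Gstm6 (-1.68, SE 0.16, adjusted p = 8.36e-08) and Gstm2 (-2.01, SE 0.22, adjusted p = 8.44e-07), each lower in 8 of 8 mice. The Gstm genes, and likewise the Cyp3a genes, are near-identical copies whose probes may be shared.

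Transport, bile acid and amino acid genes were also among those that fell. Slco1a4, an organic anion uptake carrier, fell by 3.89 (SE 0.46, adjusted p = 2.24e-06), and Abcc3, an export pump of conjugated organic anions, fell by 2.12 (SE 0.22, adjusted p = 4.00e-07), each in 8 of 8 mice. Cyp27a1, the sterol 27-hydroxylase, fell by 0.63 (SE 0.10, adjusted p = 0.000165). The bile acid synthesis and transport list had 6 of 24 members lower, 1 higher and 17 that did not pass. Of this list, 9 were lower and 1 higher when adjusted over the list alone (median -0.24, camera adjusted p = 1.01e-08, 0.0358 with an estimated correlation). When mice 59 and 60 were left out, 4 of its members fell and none rose. The member that rose was the oxysterol hydroxylase Cyp7b1 (log2 fold change 1.65, SE 0.44, adjusted p = 0.0331, 8 of 8 mice), whose rise was 1.51 without mice 59 and 60 (adjusted p = 0.127) and 1.43 without mouse 5 of the chow group (adjusted p = 0.0834). Of 33 genes for amino acid catabolism and the urea cycle 10 fell, 1 rose and 22 did not pass. Of this list, 18 fell and 2 rose when adjusted over the list alone (median -0.33, camera adjusted p = 1.64e-13, 0.0736 with an estimated correlation). The number that fell was 4 without mice 59 and 60, and with any 1 mouse left out it ran from 4 to 12. Cth, the enzyme that makes cysteine from cystathionine, fell by 1.24 (SE 0.19, adjusted p = 0.000100, 8 of 8 mice), Gnmt by a log2 fold change of -0.67 (SE 0.13, adjusted p = 0.00308, 8 of 8) and Oat by one of -0.81 (SE 0.17, adjusted p = 0.00385, 7 of 8). Etnppl, the ethanolamine-phosphate phospho-lyase, fell by 2.93 (SE 0.46, adjusted p = 0.000223, 8 of 8).

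The largest fall was that of Cyp4a14 (Entrez 13119, chromosome 4, 115486200 to 115496142), a PPAR-alpha target that encodes a fatty acid omega-hydroxylase. It lay at 14.84 ± 0.72 on chow (n = 7) and at 9.88 ± 1.67 on the high-fat diet (n = 8), which was 31.0-fold lower (log2 fold change -4.95, SE 0.76, adjusted p = 0.000135, 8 of 8 mice). The PPAR-alpha targets as a list were mixed: 7 of 26 fell, 2 rose and 17 did not pass (median -0.08, camera adjusted p = 0.0213, 0.487 with an estimated correlation). Cyp2b9 (Entrez 13094, chromosome 7, 26173409 to 26210661), a cytochrome P450 that is higher in female than in male mouse liver, fell by 2.93 (SE 0.67, adjusted p = 0.0120, 8 of 8 mice), with a log2 fold change of -2.72 without mice 59 and 60 (adjusted p = 0.0565). On chow it lay at 10.26 to 11.20 in mice 3, 4 and 5 and at 6.80 to 7.75 in the other 4, so these 3 mice carry much of the fall. Of 23 measured genes known as female-biased in mouse liver 7 fell, none rose and 16 did not pass. Of this list, 9 fell when adjusted over the list alone (median -0.27, camera adjusted p = 2.95e-14, 0.00375 with an estimated correlation). Those with the smallest p were Cyp3a16 (-2.12, SE 0.15, adjusted p = 2.14e-10), Cyp3a44 (-2.66, SE 0.22, adjusted p = 6.02e-09) and Cyp2c40 (-0.54, SE 0.10, adjusted p = 0.00113), each lower in 8 of 8 mice. Cyp3a16 and Cyp3a44 may share probes with the brighter Cyp3a11, which fell as well. The number that fell was 5 without mice 59 and 60. The female-biased list shares 4 members with the xenobiotic metabolism list, Cyp2b9 and Cyp2c40 among them, so the falls of both lists are not fully separate evidence.

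Fewer genes rose than fell at 1 week, and several of the largest rises were in genes of inflammation. Saa2 and Saa1 (chromosome 7, 46751833 to 46754314 and 46740499 to 46742980; Entrez 20209 and 20208), near-identical acute phase genes whose probes may be shared, rose by 3.98 (SE 1.07, adjusted p = 0.0350) and 3.54 (SE 0.85, adjusted p = 0.0169), each in 8 of 8 mice. Saa2 lay at 10.18 ± 1.10 on chow (n = 7) and at 14.16 ± 2.82 on the high-fat diet (n = 8). Mice 59 and 60 held the highest values, at 18.31 and 17.95. Without both mice the rises were 2.66 for Saa2 and 2.64 for Saa1, with adjusted p = 0.216 and 0.115, and without mouse 59 alone Saa2 rose by 3.39 (adjusted p = 0.0889). On chow at 12 weeks mice 43, 48 and 41 had Saa2 at 16.50, 15.30 and 13.97, so high values occurred without the high-fat diet as well. Steap4, a metalloreductase, rose by 1.90 (SE 0.43, adjusted p = 0.00979), Il1r1, the interleukin-1 receptor, by 1.85 (SE 0.30, adjusted p = 0.000304) and Saa4 by 0.85 (SE 0.19, adjusted p = 0.00826), each in 8 of 8 mice. Saa4 rose by 0.60 without mice 59 and 60 (adjusted p = 0.0569), and Steap4 had an adjusted p of 0.0791 in a fit to both groups of 1 week alone. Of 27 acute phase genes 8 rose, none fell and 19 did not pass. Of this list, 13 rose when adjusted over the list alone (median 0.77, camera adjusted p = 1.42e-11, 0.179 with an estimated correlation). The number that rose was 2 without mice 59 and 60, where the median of the whole list went from 0.77 to 0.16. With the clock gene score as a covariate it was 15, and with any 1 mouse left out it ran from 4 to 10. The acute phase score per array did not pass between the diets at 1 week (difference 0.96, exact permutation p = 0.0701, 0.108 adjusted over 20 tests). By the same test the scores of interferon genes (1.02, adjusted p = 0.00777) and Kupffer cell markers (0.91, adjusted p = 0.0311) did.

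Interferon response genes rose in 15 of 32 cases, with none that fell and 17 that did not pass. Of this list, 25 rose when adjusted over the list alone (median 0.40, camera adjusted p = 6.97e-24, 0.0177 with an estimated correlation). The antiviral genes Oas1a (0.79, SE 0.13, adjusted p = 0.000465, 8 of 8 mice), Mx2 (0.76, SE 0.14, adjusted p = 0.00136, 8 of 8), Mx1 (0.39, SE 0.08, adjusted p = 0.00293, 8 of 8) and Parp14 (0.60, SE 0.12, adjusted p = 0.00308, 7 of 8) had the smallest p. Mx1 and Mx2 are related copies whose probes may be shared. Leaving out mice 59 and 60 gave 8 that rose, and with the clock gene score as a covariate it was 17. Markers of Kupffer cells, the resident macrophages of the liver, rose in 3 of 16 cases with 13 that did not pass. Of this list, 10 rose when adjusted over the list alone (median 0.51, camera adjusted p = 1.09e-08, 0.140 with an estimated correlation). They included Cd5l (1.16, SE 0.26, adjusted p = 0.0116, 7 of 8 mice) and the complement gene C1qa (0.71, SE 0.18, adjusted p = 0.0246, 8 of 8). Leaving out mice 59 and 60, these rises were 0.86 and 0.54 (adjusted p = 0.0842 and 0.148), and without mouse 60 alone that of C1qa was 0.62 (adjusted p = 0.0627). Without mice 59 and 60 limma called 0 Kupffer markers, with 7 at an unadjusted p under 0.05, and with the clock gene score as a covariate 4 rose. With any 1 mouse left out 1 to 4 rose. Markers of recruited and lipid-associated macrophages rose in 6 of 21 cases and 1 fell (camera adjusted p = 2.87e-06, 0.0981 with an estimated correlation), and leaving out mice 59 and 60 gave 0 that rose, with 9 at an unadjusted p under 0.05. Stellate cell and fibrosis genes rose in 2 of 28 cases (camera adjusted p = 1.82e-05, 0.292 with an estimated correlation). Over the marker lists of other cell types, neutrophil markers rose in 3 of 14 cases (camera adjusted p = 2.61e-07, 0.0714 with an estimated correlation), and endothelial markers fell in 1 of 19 (camera adjusted p = 0.000728, 0.413 with an estimated correlation). Cell cycle genes rose in 1 of 28 cases (camera adjusted p = 1.15e-06, 0.314 with an estimated correlation). At an unadjusted p under 0.05 13 of them were higher, and 1 without mice 59 and 60. Mice 59 and 60 had the highest neutrophil scores (2.18 and 1.72) and cell cycle scores (2.13 and 1.67) of their group.

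Among the other genes with large rises at 1 week were Ces4a, a carboxylesterase (2.01, SE 0.35, adjusted p = 0.000896), Slc22a7, an organic anion transporter (1.91, SE 0.44, adjusted p = 0.0114), and Scara5, a ferritin receptor (1.63, SE 0.27, adjusted p = 0.000372), each higher in 8 of 8 mice. By limma 1042 genes changed, 365 higher and 677 lower, a share of 35% higher that was 19.6% once array medians were centred. Of these 873 were protein coding and 376 changed by at least 1.5-fold. At an unadjusted p under 0.05 the count was 4759, against 1812.4 from chance alone. Camera called 21 of 34 gene lists, 7 higher and 14 lower, and 8 of them with an estimated correlation. Without mouse 6 of the chow group 625 genes changed. Without mice 59 and 60, which were picked by their measured values, 568 did, 118 higher and 450 lower.

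**Figure D1:**
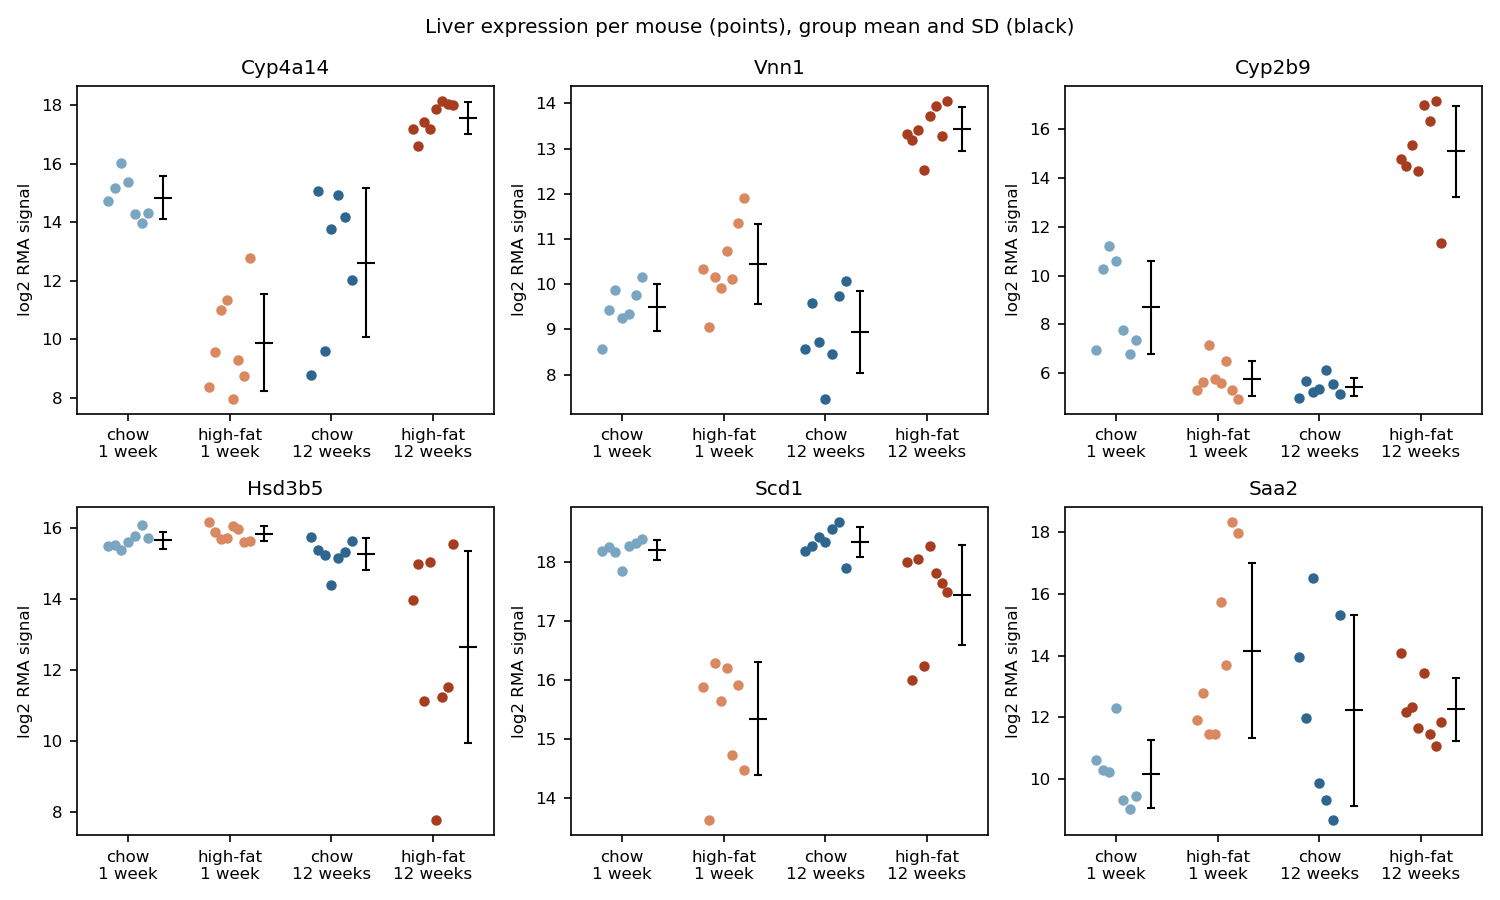
Log2 RMA signal of Cyp4a14, Vnn1, Cyp2b9, Hsd3b5, Scd1 and Saa2 in each mouse (points) of the 4 groups, with the group mean and SD in black. Cyp4a14 lay at a mean of 9.88 on the high-fat diet at 1 week and 17.55 at 12 weeks, and Saa2 spread widely in the high-fat group of 1 week and in the chow group of 12 weeks.

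The same comparison after 12 weeks asked which genes differed once the diet had been fed for longer. Genes of fatty acid oxidation, PPAR-alpha targets and lipid storage genes were higher on the high-fat diet. Cyp4a14 lay at 12.61 ± 2.56 on chow (n = 7) and at 17.55 ± 0.54 on the high-fat diet (n = 8), a rise of 4.93 (SE 0.76, adjusted p = 6.16e-05, 8 of 8 mice). Without chow mice 41 and 43, at 8.77 and 9.60, the rise was 3.56 (adjusted p = 0.000318). Vnn1, a pantetheinase and PPAR-alpha target (Entrez 22361, chromosome 10, 23894688 to 23905343), rose 22.5-fold (log2 fold change 4.49, SE 0.35, adjusted p = 4.29e-10, 8 of 8 mice). Of 26 PPAR-alpha targets 22 rose, none fell and 4 did not pass. Of this list, 25 rose when adjusted over the list alone (median 1.12, camera adjusted p = 9.64e-37, 0.000458 with an estimated correlation). Examples were the acyl-CoA thioesterase Acot2 (2.79, SE 0.27, adjusted p = 2.37e-08) and the lipid droplet coat gene Plin2 (1.29, SE 0.15, adjusted p = 5.82e-07), each higher in 8 of 8 mice. Cyp4a and Acot genes are near-identical copies whose probes may be shared.

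Fatty acid oxidation genes of mitochondria and peroxisomes rose in 23 of 29 cases, none fell and 6 did not pass. Of this list, 28 rose when adjusted over the list alone (median 0.59, camera adjusted p = 2.07e-32, 0.00385 with an estimated correlation). Pex11a, a gene of peroxisome division, rose by 1.76 (SE 0.17, adjusted p = 2.41e-08), and the beta-oxidation genes Eci1, Hadh and Decr1 rose by 0.95, 0.84 and 0.95 (SE 0.09, 0.09 and 0.10), with adjusted p = 3.01e-08, 1.18e-07 and 1.20e-07, each in 8 of 8 mice. In the list of lipid droplet and lipid uptake genes 16 of 25 rose, 1 fell and 8 did not pass. Of this list, 19 rose and 1 fell when adjusted over the list alone (median 0.69, camera adjusted p = 4.11e-18, 0.00214 with an estimated correlation). Adipocyte markers, which share 3 genes with it, rose in 5 of 14 cases (camera adjusted p = 0.000133, 0.0564 with an estimated correlation). Cd36, a fatty acid uptake receptor (Entrez 12491, chromosome 5, 17781690 to 17888959), rose 10.1-fold from 10.55 ± 0.65 (n = 7) to 13.88 ± 0.70 (n = 8; log2 fold change 3.33, SE 0.24, adjusted p = 7.91e-11, 8 of 8 mice). Fabp2, an intracellular fatty acid binding protein gene, rose by 2.03 (SE 0.14, adjusted p = 4.42e-11), Mogat1, an enzyme of triglyceride synthesis, by 0.93 (SE 0.08, adjusted p = 2.13e-09) and Mgll, the monoglyceride lipase, by 1.51 (SE 0.16, adjusted p = 8.28e-08), each in 8 of 8 mice. Mfsd2a, a lysophospholipid transporter, rose 44.1-fold (log2 fold change 5.46, SE 0.51, adjusted p = 9.94e-09, 8 of 8 mice). Rgs16, a regulator of G protein signalling, rose by 4.53 (SE 1.09, adjusted p = 0.0104, 8 of 8), and by 3.39 without mice 41 and 43 of the chow group (adjusted p = 0.0814). Serpina7, which encodes thyroxine-binding globulin, rose by 2.90 (SE 0.42, adjusted p = 2.64e-05, 8 of 8).

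Some genes whose level differs between the sexes in mouse liver changed at 12 weeks. Cyp2b9 rose from 5.42 ± 0.38 on chow (n = 7), a level near the array medians, to 15.09 ± 1.88 on the high-fat diet (n = 8; log2 fold change 9.67, SE 0.67, adjusted p = 4.42e-11, 8 of 8 mice), and Cyp2b13 rose by 3.86 (SE 0.44, adjusted p = 6.00e-07, 8 of 8). These are near-identical copies whose probes may be shared. In the female-biased list 8 of 23 rose, 2 fell and 13 did not pass. The list shares 4 members with the xenobiotic metabolism list and 1 each with the PPAR-alpha, fatty acid oxidation and lipid uptake lists. Of this list, 9 rose and 2 fell when adjusted over the list alone (median 0.22, camera adjusted p = 0.000495, 0.229 with an estimated correlation). Cyp3a16 was one of those that fell (-1.70, SE 0.15, adjusted p = 3.09e-09, 8 of 8 mice), and it may share probes with Cyp3a11, which fell as well. Of 19 male-biased genes 11 fell, none rose and 8 did not pass. Of this list, 15 fell when adjusted over the list alone (median -1.17, camera adjusted p = 1.33e-20, 0.0143 with an estimated correlation). Gstp1, a glutathione transferase, fell by 1.77 (SE 0.14, adjusted p = 4.86e-10). Cyp2c70, which makes muricholic acids in mice, changed by a log2 fold change of -1.61 (SE 0.17, adjusted p = 8.18e-08), Dhrs9 by one of -1.66 (SE 0.28, adjusted p = 0.000197) and Selenbp2 by one of -1.82 (SE 0.31, adjusted p = 0.000221), each in 8 of 8 mice. Hsd3b5, a steroid dehydrogenase gene of male liver (Entrez 15496, chromosome 3, 98618634 to 98645534), lay at 15.28 ± 0.44 on chow (n = 7) and at 12.66 ± 2.69 on the high-fat diet (n = 8; log2 fold change -2.62, SE 0.69, adjusted p = 0.0188, 7 of 8 mice). Moxd1, another male-biased gene, lay at 9.64 ± 3.81 and 5.63 ± 1.08 (SE of the difference 1.05, adjusted p = 0.0190), with 3 of the 7 chow mice near background. Without mice 41 and 43, picked for their low Cyp4a14, 7 male-biased genes fell. The log2 fold change of Hsd3b5 then stayed at -2.53 (adjusted p = 0.0550), while that of Moxd1 went from -4.02 to -2.56 (adjusted p = 0.151) and was -3.43 without mouse 41 alone (adjusted p = 0.0545).

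Amino acid catabolism and urea cycle genes fell in 16 of 33 cases, 1 rose and 16 did not pass. Of this list, 21 fell and 4 rose when adjusted over the list alone (median -0.39, camera adjusted p = 1.28e-13, 0.118 with an estimated correlation). Asns, the asparagine synthetase, fell by 2.92 (SE 0.34, adjusted p = 9.22e-07). Cps1, the entry enzyme of the urea cycle, changed by a log2 fold change of -0.66 (SE 0.11, adjusted p = 0.000184), Gnmt by one of -0.74 (SE 0.13, adjusted p = 0.000511) and Gls2, the liver glutaminase, by one of -1.33 (SE 0.24, adjusted p = 0.000652), each in 8 of 8 mice. Adgrf1, an adhesion G protein-coupled receptor, fell to 5.87, near background (log2 fold change -4.30, SE 0.34, adjusted p = 5.25e-10), and Csad, an enzyme of taurine synthesis, was 10.4-fold lower (-3.38, SE 0.32, adjusted p = 1.17e-08), each in 8 of 8 mice. Cyp3a11 fell by 2.75 (SE 0.26, adjusted p = 1.03e-08), Cyp2c55 by a log2 fold change of -2.77 (SE 0.27, adjusted p = 2.00e-08) and the carboxylesterase Ces2a by one of -2.65 (SE 0.19, adjusted p = 4.42e-11), each in 8 of 8 mice. The xenobiotic metabolism list as a whole had 6 members higher and 7 lower (camera adjusted p = 0.167). Glutathione and NRF2 target genes fell in 8 of 26 cases, 2 rose and 16 did not pass. Of this list, 10 fell and 4 rose when adjusted over the list alone (median -0.09, camera adjusted p = 0.000975, 0.369 with an estimated correlation). With any 1 mouse left out 4 to 9 fell. Ugdh (-0.82, SE 0.15, adjusted p = 0.000886) and Gsta2 (-1.27, SE 0.30, adjusted p = 0.00763) were lower in 8 of 8 mice.

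Markers of recruited and lipid-associated macrophages rose in 5 of 21 cases, 1 fell and 15 did not pass. Of this list, 11 rose and 1 fell when adjusted over the list alone (median 0.21, camera adjusted p = 3.90e-05, 0.229 with an estimated correlation). Mmp12 rose by 0.78 (SE 0.14, adjusted p = 0.000411), Clec7a by 1.03 (SE 0.21, adjusted p = 0.00224) and Gpnmb by 0.49 (SE 0.10, adjusted p = 0.00228), each in 8 of 8 mice. Markers of other cells moved the same way by camera. They were stellate cell and fibrosis genes (0 of 28 called, 12 higher at an unadjusted p under 0.05, camera adjusted p = 9.26e-05, 0.455 with an estimated correlation), endothelial markers (1 of 19, camera adjusted p = 0.0128, 0.752 with an estimated correlation) and cholangiocyte markers (2 of 16, camera adjusted p = 0.0416, 0.409 with an estimated correlation). At 12 weeks limma called 0 Kupffer cell markers, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.247), and 0 acute phase genes, with 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00341, 0.752 with an estimated correlation). It called 0 cholesterol synthesis genes, with 1 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.190), and fatty acid synthesis genes passed in 3 cases higher and 3 lower (camera adjusted p = 0.681). Interferon response genes rose in 5 of 32 cases (camera adjusted p = 0.000543, 0.588 with an estimated correlation). In total 2005 genes changed by limma, 1153 higher and 852 lower. The share that was higher, 57.5%, was 28.7% once array medians were centred, so the balance of rises and falls is not settled. Of all these genes 1499 were protein coding and 597 changed by at least 1.5-fold. At an unadjusted p under 0.05 the count was 6674. Camera called 17 of 34 lists, 11 higher and 6 lower, and 4 with an estimated correlation. A fit to the arrays of 12 weeks alone gave 1313 genes, in which Hsd3b5 and Moxd1 had adjusted p = 0.133 and 0.0871.

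**Figure D2:**
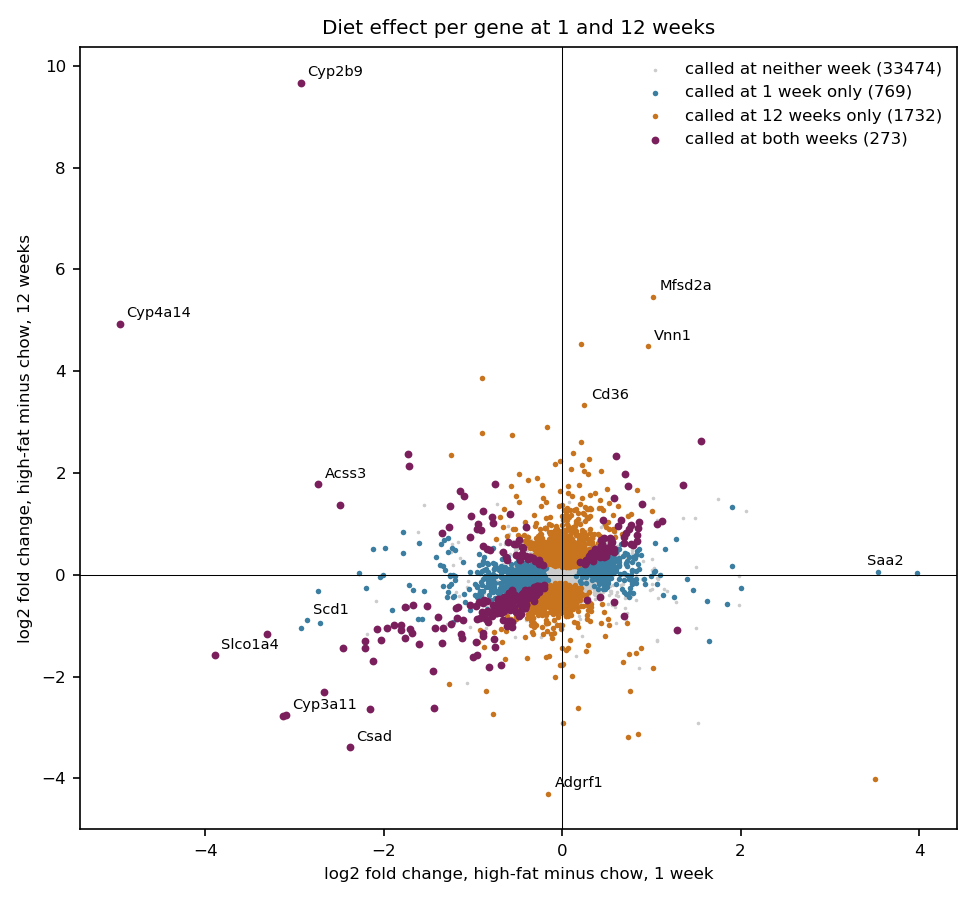
Log2 fold change of each gene on the high-fat diet against chow at 1 week (horizontal axis) and at 12 weeks (vertical axis), with colours for the weeks at which limma called it. Cyp4a14 and Cyp2b9 lay lower at 1 week and higher at 12 weeks, at -4.95 and 4.93 and at -2.93 and 9.67, while Cyp3a11 was lower at both, at -3.09 and -2.75.

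Whether the response to the diet differed between 1 and 12 weeks was tested as the difference between both diet effects. Cyp2b9 differed by 12.60 (SE 0.95, adjusted p = 8.64e-10), a lower bound, since its means of 5.77 on the high-fat diet at 1 week and 5.42 on chow at 12 weeks lay near background. Cyp4a14 differed by 9.89 (SE 1.07, adjusted p = 1.62e-06; 8.52 without mice 41 and 43), and both had turned from a fall to a rise. Acss3, an acyl-CoA synthetase, differed by 4.52 (SE 0.34, adjusted p = 8.64e-10), from -2.73 at 1 week to 1.79 at 12 weeks. Cyp2b13 differed by 4.75 (SE 0.63, adjusted p = 2.28e-05) and Mfsd2a by 4.44 (SE 0.72, adjusted p = 0.000293). Lower at 12 weeks than at 1 week was the diet effect on Moxd1 (-7.52, SE 1.49, adjusted p = 0.00317), Adgrf1 (-4.14, SE 0.49, adjusted p = 3.84e-06), Cyp7b1 (-2.94, SE 0.62, adjusted p = 0.00577), Asns (-2.93, SE 0.49, adjusted p = 0.000436) and Selenbp2 (-2.84, SE 0.43, adjusted p = 0.000146). The diet effects themselves had been 0.01 at 1 week and -2.92 at 12 weeks for Asns, and -0.16 and -4.30 for Adgrf1. On chow Asns rose by 2.11 from 1 to 12 weeks (adjusted p = 0.00131 by limma, 0.0588 in a fit to both chow groups alone). Much of its difference thus lay in the chow groups.

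Of the gene lists, fatty acid oxidation had 20 of 29 members with a higher diet effect at 12 weeks, none with a lower one and 9 that did not pass. Of this list, 25 had a higher effect when adjusted over the list alone (median 0.71, camera adjusted p = 2.78e-39, 0.00121 with an estimated correlation). Ehhadh, a peroxisomal beta-oxidation enzyme, differed by 1.72 (SE 0.23, adjusted p = 2.53e-05), Eci1 by 1.02 (SE 0.13, adjusted p = 1.77e-05) and Hadh by 0.95 (SE 0.13, adjusted p = 2.28e-05). PPAR-alpha targets had 17 of 26 higher and 9 that did not pass. Of this list, 20 had a higher effect when adjusted over the list alone (median 1.22, camera adjusted p = 1.72e-38, 0.000348 with an estimated correlation). Acot1 and Acot2 were among them, at 2.79 and 3.69 (SE 0.32 and 0.38, adjusted p = 2.39e-06 and 8.13e-07). Fatty acid synthesis genes had 11 of 26 higher and 15 that did not pass. Of this list, 16 had a higher effect when adjusted over the list alone (median 0.85, camera adjusted p = 6.00e-16, 0.0263 with an estimated correlation). Me1 differed by 2.42 (SE 0.36, adjusted p = 0.000115), Elovl6 by 2.23 (SE 0.34, adjusted p = 0.000130) and Elovl5 by 1.46 (SE 0.24, adjusted p = 0.000423). Glutathione and NRF2 targets had 10 of 26 higher, 1 lower and 15 that did not pass. Of this list, 16 were higher and 1 lower when adjusted over the list alone (median 0.66, camera adjusted p = 3.51e-11, 0.0230 with an estimated correlation). Gstt1 was higher by 1.76 (SE 0.23, adjusted p = 2.28e-05) and Entpd5 by 1.29 (SE 0.18, adjusted p = 5.35e-05), and Gstp1 was the member that was lower (-1.77, SE 0.20, adjusted p = 2.22e-06).

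The sex-biased lists differed in opposite ways. Female-biased genes had 9 of 23 members with a higher diet effect at 12 weeks, none with a lower one and 14 that did not pass. Of this list, 15 had a higher effect when adjusted over the list alone (median 0.46, camera adjusted p = 5.08e-21, 0.000452 with an estimated correlation). Cd36, which is also in the lipid droplet and lipid uptake list, differed by 3.08 (SE 0.34, adjusted p = 1.88e-06). Male-biased genes had 8 of 19 with a lower effect and 11 that did not pass. Of this list, 13 had a lower effect when adjusted over the list alone (median -1.04, camera adjusted p = 5.08e-21, 0.0107 with an estimated correlation). Limma called 761 genes for this difference, 582 higher and 179 lower (76.5% higher, 63.2% after a repeated quantile normalization), with 602 protein coding and 504 differing by at least 1.5-fold, and 4141 at an unadjusted p under 0.05. Camera called 21 lists, 15 higher and 6 lower, and 8 with an estimated correlation. Of the genes called at both weeks, 63 were higher at both, where independent lists would share 11.6, and 156 were lower at both, where they would share 15.9. A further 49 had turned from lower to higher (21.5 from independent lists), among them Pparg, Pklr and Khk, which were chosen for naming after their values were seen. The 5 that had turned from higher to lower (8.6 from independent lists), likewise named after their values were seen, were C6, C9, Hc, Fgfr1 and Plxnb1. The numbers from independent lists take genes to move separately from each other, which genes of 1 tissue need not do. Across genes, which are not independent replicates, the diet effects at both weeks correlated with Pearson's r = 0.17 and a jackknife SE over the mice of 0.08. Of 100 permutations of diet within week, the real one included, 14 gave a correlation as large, so chance cannot be excluded for it.

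**Figure D3:**
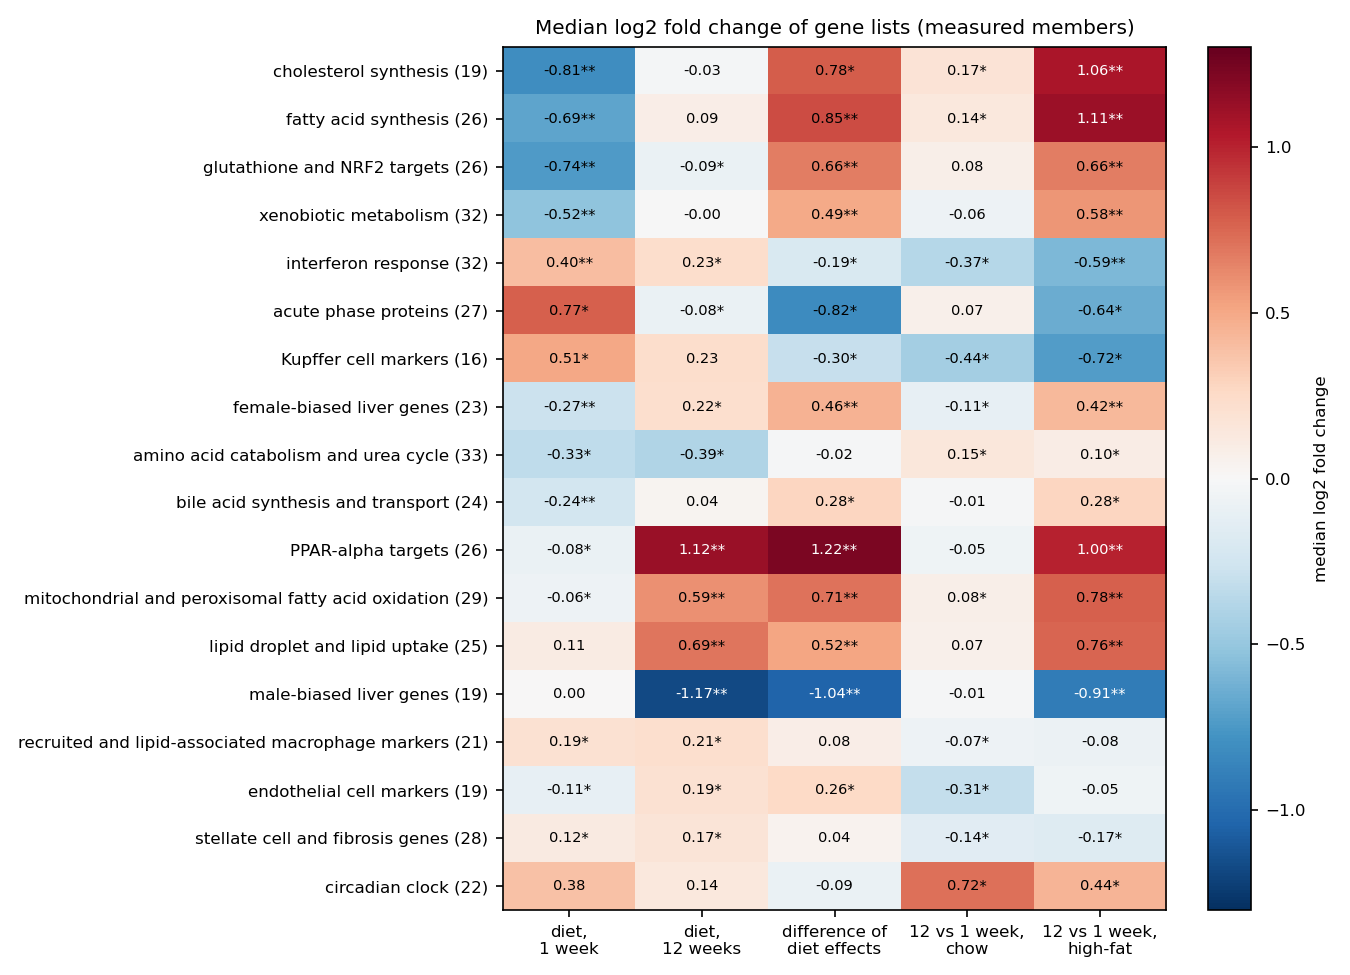
Median log2 fold change of the measured members (number in brackets) of 18 gene lists in the 5 comparisons. A single star marks an adjusted p under 0.05 by camera with its preset correlation, and a double star one that also holds with an estimated correlation: cholesterol synthesis lay at -0.81 at 1 week, at -0.03 at 12 weeks and at 1.06 for time on the high-fat diet.

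Between 1 and 12 weeks on chow the comparison asked what changed without the high-fat diet. Age, collection week and any array batch cannot be told apart here. Moxd1 lay at 4.93 to 5.36 in all mice of 1 week, near background, and at 12 weeks at 11.64 to 13.39 in 4 mice and at 5.16, 5.48 and 6.24 in the other 3. Its mean rise was 4.50 (SE 1.09, adjusted p = 0.0404, 0.167 in a fit to both chow groups alone). The pseudogenes Gtpbp4-ps1 and Gtpbp4-ps4 rose by 3.76 (SE 0.63, adjusted p = 0.00130) and 2.23 (SE 0.40, adjusted p = 0.00249), and Asns by 2.11 (SE 0.36, adjusted p = 0.00131, 0.0588 in that fit), each in 7 of 7 mice. The pseudogenes are near-identical copies whose probes may be shared. Cyp2b9 fell by 3.28 (SE 0.70, adjusted p = 0.0150), much of it from mice 3, 4 and 5 of the 1-week group, Ndrg1 by a log2 fold change of -2.02 (SE 0.23, adjusted p = 4.11e-06), the vasopressin receptor Avpr1a by one of -1.26 (SE 0.31, adjusted p = 0.0437) and the zinc importer Slc39a4 by one of -1.26 (SE 0.21, adjusted p = 0.00137), each in 7 of 7 mice. The changes were 3.88 for Moxd1 without mouse 43 of the 12-week group (adjusted p = 0.101), -2.86 for Cyp2b9 without mouse 4 of the 1-week group (adjusted p = 0.0526) and -1.15 for Avpr1a without mouse 47 of the 12-week group (adjusted p = 0.118). Without mice 41 and 43 they were 3.05 for Moxd1 (adjusted p = 0.189) and -3.15 for Cyp2b9 (adjusted p = 0.0527).

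Interferon response genes fell in 5 of 32 cases with 27 that did not pass. Of this list, 17 fell when adjusted over the list alone (median -0.37, camera adjusted p = 6.81e-24, 0.0596 with an estimated correlation). With any 1 mouse left out 3 to 5 fell. Usp18 (-1.22, SE 0.17, adjusted p = 9.78e-05), Ifi44 (-1.05, SE 0.18, adjusted p = 0.00130) and Rsad2 (-0.93, SE 0.16, adjusted p = 0.00140) were lower in 7 of 7 mice. Endothelial markers fell in 2 of 19 cases. Of this list, 10 fell when adjusted over the list alone (median -0.31, camera adjusted p = 5.78e-15, 0.142 with an estimated correlation). These were the endothelial cadherin Cdh5 (-0.59, SE 0.14, adjusted p = 0.0341) and the scavenger receptor Stab2 (-0.62, SE 0.13, adjusted p = 0.0129), each lower in 7 of 7 mice, and Cdh5 fell by 0.56 without mouse 7 of the 1-week group (adjusted p = 0.0831). In the fit to both chow groups alone it was 0.196 for Cdh5 and 0.103 for Stab2. Mouse 45 of the 12-week group had the lowest endothelial score, -2.94, against -1.24 to 0.28 in the others, and without it 2 endothelial markers fell with a list median of -0.22. The number ran from 1 to 3 with any 1 mouse left out. Stellate cell and fibrosis genes fell in 3 of 28 cases. Of this list, 12 fell when adjusted over the list alone (median -0.14, camera adjusted p = 1.03e-11, 0.142 with an estimated correlation). These were Sparc (-1.04, SE 0.13, adjusted p = 3.65e-05), Fbn1 (-0.41, SE 0.08, adjusted p = 0.00634) and Mmp2 (-0.65, SE 0.15, adjusted p = 0.0255), in 7 of 7 mice. Mmp2 fell by 0.60 without mouse 45 of the 12-week group (adjusted p = 0.0730) and by 0.62 without mice 41 and 43 (adjusted p = 0.0731). Kupffer cell markers (camera adjusted p = 1.61e-05, 0.445 with an estimated correlation) and lymphocyte markers (camera adjusted p = 3.83e-05, 0.142 with an estimated correlation) were lower by camera as well, with 0 called by limma and 8 and 6 at an unadjusted p under 0.05. So were the lists of antigen presentation (camera adjusted p = 0.00827, 0.544 with an estimated correlation), recruited macrophages (camera adjusted p = 0.0197, 0.624 with an estimated correlation) and cholangiocytes (camera adjusted p = 0.0393, 0.445 with an estimated correlation). In the circadian clock list 1 of 22 genes rose and 21 did not pass. Of this list, 13 rose and 4 fell when adjusted over the list alone (median 0.72, camera adjusted p = 0.000297, 0.142 with an estimated correlation). The gene that rose was Noct, a deadenylase-related gene with a daily rhythm (1.38, SE 0.29, adjusted p = 0.0131, 0.0586 in the fit to both chow groups, 6 of 7 mice), and Bhlhe41 lay at 5.37 ± 0.30 and 6.62 ± 1.18 (difference 1.25, SE 0.33, adjusted p = 0.0708, 7 of 7 mice). Bhlhe41 passed with array weights and with the filter at the median signal (adjusted p = 0.0422 each). It also passed without mice 41 and 43 (1.69, adjusted p = 0.00571), but under no other alternative.

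A score of clock phase per array, from genes with peaks at opposite times of day, was -1.82 ± 0.92 (SD) in the chow group at 1 week and 0.31 ± 2.12 at 12 weeks (exact permutation p = 0.0396, 0.0721 adjusted over 20 tests). The differences were of similar size between the diets at 1 week (1.63, exact permutation p = 0.0311, adjusted 0.0691) and between the weeks on the high-fat diet (1.71, exact permutation p = 0.0361, adjusted 0.0721). Between the diets at 12 weeks it was 1.21 (exact permutation p = 0.195, adjusted 0.229), and none of the 4 passed once adjusted. With this score as a covariate the change of Noct went from 1.38 to 0.91 (adjusted p = 0.174) and that of Avpr1a from -1.26 to -0.71 (adjusted p = 0.409). Those of Cdh5 and Mmp2 stayed at -0.58 and -0.67 though their calls were lost (adjusted p = 0.112 and 0.0720), and 4 interferon genes fell. Limma called 255 genes on chow, 144 higher and 111 lower, with 169 protein coding, 140 changed by at least 1.5-fold and 3565 at an unadjusted p under 0.05. With the clock gene score as a covariate the count was 158, and without mouse 4 of the 1-week group it was 157. Camera called 15 lists, 5 higher and 10 lower, and 0 of them with an estimated correlation. The direction test fry, which asks whether the genes of a list move together one way and not whether they differ from other genes or lists, called 6.

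**Figure D4:**
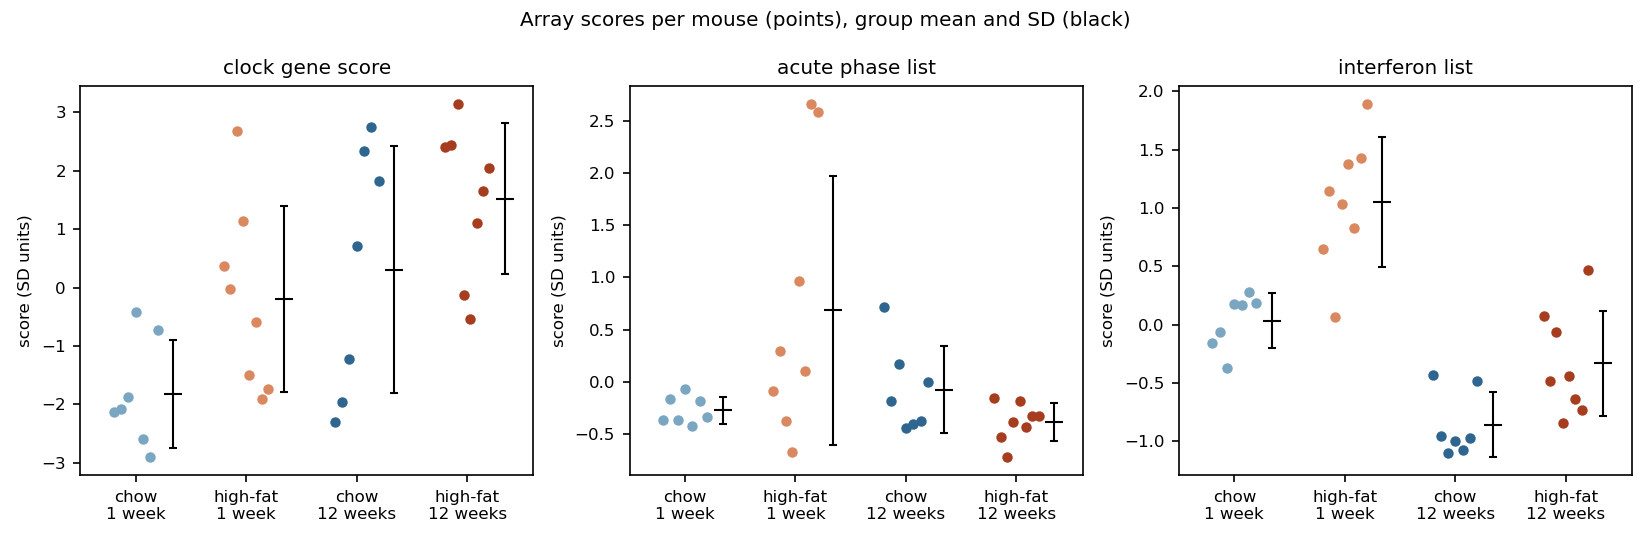
Scores per mouse (points) for the clock genes, the acute phase list and the interferon list in the 4 groups, in units of the SD across arrays, with the group mean and SD in black. The clock gene score averaged -1.82 on chow and -0.19 on the high-fat diet at 1 week, and in that high-fat group the acute phase score was highest in mice 59 and 60, at 2.66 and 2.58.

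On the high-fat diet the comparison of 12 weeks with 1 week asked which genes changed as feeding went on, with age and batch included. It shares its groups with the diet comparisons and is not an independent test of them. Mfsd2a rose by 6.53 (SE 0.49, adjusted p = 7.03e-11), Acss3 by 4.08 (SE 0.23, adjusted p = 2.44e-13), Cyp2b9 by 9.32 (SE 0.65, adjusted p = 2.65e-11), Cyp4a14 by 7.67 (SE 0.73, adjusted p = 8.53e-09) and Rgs16 by 4.23 (SE 1.06, adjusted p = 0.00681), each in 8 of 8 mice. With the clock gene score as a covariate Rgs16 rose by 2.24 (adjusted p = 0.0511). Adgrf1 fell by 4.49 (SE 0.33, adjusted p = 6.04e-11), Hsd3b5 by a log2 fold change of -3.19 (SE 0.66, adjusted p = 0.00115), Ces4a by one of -2.92 (SE 0.34, adjusted p = 3.42e-07), Selenbp2 by one of -2.73 (SE 0.30, adjusted p = 8.22e-08) and the fatty acid binding protein gene Fabp5 by one of -2.56 (SE 0.43, adjusted p = 7.71e-05), each in 8 of 8 mice.

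Fatty acid oxidation genes rose in 27 of 29 cases, with none that fell and 2 that did not pass. Of this list, 28 rose when adjusted over the list alone (median 0.78, camera adjusted p = 2.80e-45, 0.000741 with an estimated correlation). Hsd17b4, the peroxisomal multifunctional enzyme, rose by 0.88 (SE 0.07, adjusted p = 8.81e-10, 8 of 8 mice). Cholesterol synthesis genes rose in 17 of 19 cases and 2 did not pass, with 17 as well adjusted over the list alone (median 1.06, camera adjusted p = 4.06e-20, 0.0221 with an estimated correlation). Hsd17b7 rose by 1.51 (SE 0.19, adjusted p = 1.24e-06) and Hmgcs1 by 1.67 (SE 0.25, adjusted p = 1.37e-05), each in 8 of 8 mice. Fatty acid synthesis genes rose in 19 of 26 cases and 7 did not pass. Of this list, 20 rose and 1 fell when adjusted over the list alone (median 1.11, camera adjusted p = 4.06e-20, 0.0118 with an estimated correlation). Me1 rose by 3.09 (SE 0.25, adjusted p = 2.87e-10) and Elovl6 by 2.35 (SE 0.23, adjusted p = 1.50e-08), each in 8 of 8 mice. PPAR-alpha targets rose in 21 of 26 cases (camera adjusted p = 5.68e-34, 0.000741 with an estimated correlation).

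Interferon response genes fell in 26 of 32 cases and 6 did not pass. Of this list, 27 fell when adjusted over the list alone (median -0.59, camera adjusted p = 4.02e-30, 0.00895 with an estimated correlation), and in 20 without mice 59 and 60. Usp18 was lower by a log2 fold change of -1.43 (SE 0.16, adjusted p = 1.69e-07), Parp14 by one of -1.01 (SE 0.12, adjusted p = 2.15e-07) and Mx2 by one of -1.15 (SE 0.14, adjusted p = 3.97e-07), each in 8 of 8 mice. Kupffer cell markers fell in 12 of 16 cases and 4 did not pass, with 12 adjusted over the list alone (median -0.72, camera adjusted p = 2.23e-11, 0.0897 with an estimated correlation), and in 6 without mice 59 and 60. Clec4f (-0.96, SE 0.18, adjusted p = 0.000366) and Folr2 (-1.11, SE 0.24, adjusted p = 0.00148) were lower in 8 of 8 mice. Among other cell types stellate cell and fibrosis genes fell in 10 of 28 cases (camera adjusted p = 1.56e-06, 0.160 with an estimated correlation). Neutrophil markers did so in 5 of 14 (camera adjusted p = 4.69e-05, 0.127 with an estimated correlation) and lymphocyte markers in 4 of 20 (camera adjusted p = 0.000917, 0.156 with an estimated correlation), while adipocyte markers rose in 4 of 14 (camera adjusted p = 0.00251, 0.109 with an estimated correlation). Acute phase genes fell in 10 of 27 cases. Of this list, 17 fell when adjusted over the list alone (camera adjusted p = 3.09e-12, 0.150 with an estimated correlation), and in 6 without mice 59 and 60. In total 3789 genes changed, 2509 higher and 1280 lower (66.2% higher, 49.8% after a repeated quantile normalization), with 2759 protein coding, 1120 changed by at least 1.5-fold and 7371 at an unadjusted p under 0.05. Camera called 24 lists, 16 higher and 8 lower, and 10 with an estimated correlation.

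Lists with no call by camera in any of the 5 comparisons were the ER stress response, immediate early genes, and the markers of the pancreas and of erythroid cells, with adjusted p between 0.346 and 0.884 for ER stress and between 0.137 and 0.830 for immediate early genes. For the acinar markers of the pancreas it lay between 0.373 and 0.997, and for erythroid markers between 0.567 and 0.953. Median and mean of a list, or either of them and the camera test, differed in sign for erythroid markers at 1 week, and at 12 weeks for sterol uptake, fatty acid synthesis, bile acid, glucose, xenobiotic and erythroid lists. They also did so for the ER stress, lymphocyte, acinar, erythroid and fetal lists in the difference of the diet effects. The same held for the bile acid, glucose, male-biased and DNA methylation lists over time on chow, and for the cholangiocyte and erythroid lists over time on the high-fat diet. The direction of the named genes did not turn under either rescaling of the arrays, and that of the described lists did not turn under the repeated quantile normalization. Centred medians moved the median log2 fold change over all genes at 12 weeks of high-fat diet only from 0.04 to -0.03. The larger changes of the named genes could hardly have turned by this.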

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

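The tests of mice 59 and 60, of mice 41 and 43, of shared probes, of the hepatocyte share and of female livers were chosen only after the results were seen, as was the clock gene score itself. Only the bounds of the clock phase tests were set before their own results were seen. Single mice far from the rest of their group, and diet effects that differed between 1 and 12 weeks, are described first. Over 400 gene and group pairs 25 had such a mouse, where chance gives about 1 in 20, or 20. Mouse 5 of the chow group of 1 week had 6 of them.

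In the chow group of 1 week some mice lay far from the others. Mouse 10 lay apart with Abcc3 at 13.63 (highest of the group, next 13.20). Mouse 5 lay apart with Cd5l at 12.19 (highest of the group, next 11.44), Clec4f at 11.32 (highest of the group, next 10.81), Gstm2 at 12.24 (lowest of the group, next 12.79), Me1 at 13.24 (lowest of the group, next 14.19), Saa1 at 14.25 (highest of the group, next 12.45) and Scd1 at 17.85 (lowest of the group, next 18.17). Mouse 6 lay apart with Cth at 16.71 (highest of the group, next 16.24).

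In the high-fat group of 1 week some mice lay far from the others. Mouse 59 lay apart with Ehhadh at 11.56 (lowest of the group, next 12.49). Mouse 60 lay apart with Gsta2 at 6.40 (lowest of the group, next 7.29). Mouse 54 lay apart with Ifi44 at 8.0 (lowest of the group, next 8.54).

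In the chow group of 12 weeks some mice lay far from the others. Mouse 48 lay apart with Acss2 at 10.10 (lowest of the group, next 11.33) and Gstm1 at 16.54 (lowest of the group, next 16.92). Mouse 45 lay apart with Cdh5 at 8.62 (lowest of the group, next 9.46). Mouse 41 lay apart with Il1r1 at 12.41 (highest of the group, next 11.48) and Scara5 at 7.93 (highest of the group, next 6.60). Mouse 43 lay apart with Mx1 at 5.61 (lowest of the group, next 5.83).

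In the high-fat group of 12 weeks some mice lay far from the others. Mouse 95 lay apart with Acot2 at 9.13 (lowest of the group, next 10.70) and Rgs16 at 9.71 (lowest of the group, next 13.11). Mouse 100 lay apart with Adgrf1 at 7.44 (highest of the group, next 6.12), Gls2 at 10.18 (lowest of the group, next 11.38) and Moxd1 at 8.14 (highest of the group, next 5.80). Mouse 98 lay apart with Gtpbp4-ps1 at 10.93 (highest of the group, next 8.64) and Gtpbp4-ps4 at 9.66 (highest of the group, next 7.98). Mouse 91 lay apart with Parp14 at 9.88 (highest of the group, next 9.61).

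Among the genes named for the diet comparisons at 1 or 12 weeks 40 had a diet effect that differed between 1 and 12 weeks by limma, 27 with a higher and 13 with a lower effect at 12 weeks, with adjusted p from 8.64e-10 to 0.0252. The log2 difference, 12 weeks minus 1 week, was 12.60 for Cyp2b9 (a lower bound), 9.89 for Cyp4a14, 4.75 for Cyp2b13, 4.44 for Mfsd2a, 3.69 for Acot2, 3.53 for Vnn1, 3.08 for Cd36 and 3.06 for Serpina7. It was 2.63 for Abcc3, 2.42 for Me1, 2.23 for Elovl6, 2.0 for Gstm2, 1.96 for Scd1, 1.60 for Fabp2, 1.57 for Pex11a and 1.51 for Hmgcs1. Smaller differences were those of Gstm1 (1.37), Gstm4 (1.12), Gstm6 (1.09), Eci1 (1.02), Plin2 (1.00), Hadh (0.95), Mgll (0.92), Decr1 (0.88), Mogat1 (0.81), Sc5d (0.55) and Acat2 (0.48). Negative differences were -7.52 for Moxd1, -4.14 for Adgrf1, -2.94 for Cyp7b1, -2.93 for Asns, -2.84 for Selenbp2, -2.42 for Il1r1 and -2.26 for Ces4a. They were -2.13 for Scara5, -1.77 for Gstp1, -1.43 for Cyp2c70, -1.02 for Mx2, -0.80 for Parp14 and -0.44 for Mx1.

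Of the lists described for the diet comparisons 13 differed between the weeks by camera, out of 21 among all lists. Adjusted p, with that from an estimated correlation after it, was 2.78e-39 (0.00121) for fatty acid oxidation, 1.72e-38 (0.000348) for PPAR-alpha targets, 5.08e-21 (0.000452) for female-biased and 5.08e-21 (0.0107) for male-biased genes. It was 9.76e-18 (0.00126) for lipid droplet genes, 6.00e-16 (0.0263) for fatty acid synthesis, 3.51e-11 (0.0230) for glutathione and NRF2 targets and 1.04e-11 (0.0230) for xenobiotic metabolism. The call was lost with an estimated correlation for acute phase genes at 4.64e-15 (0.137), cholesterol synthesis at 2.83e-13 (0.0835), interferon genes at 5.34e-06 (0.270), Kupffer cell markers at 0.000983 (0.420) and bile acid genes at 0.00162 (0.237). It was also lost for all 8 other lists, with endothelial markers at 2.46e-06 (0.237), oxidative phosphorylation at 0.000207 (0.429), lipoproteins at 0.000826 (0.177) and glucose metabolism at 0.00162 (0.184). The rest were neutrophil markers at 0.00435 (0.295), sterol uptake at 0.0151 (0.129), adipocyte markers at 0.0156 (0.193) and DNA methylation genes at 0.0166 (0.172).

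Acute phase (8 of 27, with 19 that did not pass, camera adjusted p = 0.179 with an estimated correlation) and interferon genes were higher at 1 week of high-fat diet. Leaving out mice 59 and 60, 2 of 8 called acute phase genes stayed called, their median rise going from 1.35 (SE 0.27) to 0.92 (SE 0.21) with fewer samples and that of the whole list from 0.77 to 0.16, so a rise in the group and a state of these mice alone cannot be told apart for this list. Of 15 interferon genes 8 stayed called without them (median 0.62 before and 0.51 after) against these mice as the whole cause. With the clock gene score as a covariate 8 of 8 acute phase and 14 of 15 interferon genes stayed called. This argues only against a relation to the score that is the same in all groups. The score holds Dbp, which ran against Saa2 within this group (r = -0.95), so for the acute phase genes the covariate cannot decide on clock phase. A lower share of hepatocytes would raise markers of other cells alike, but the Kupffer minus endothelial score differed between the diets by 1.40 (two-sided exact permutation p = 0.0107, over 6435 regroupings), a test not repeated without mice 59 and 60. Diet, or infection or handling of single animals, may each contribute and were not tested.

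PPAR-alpha targets had a higher diet effect at 12 weeks than at 1 week. With the clock gene score as a covariate 17 of 17 called members stayed called. The score differed between the diets by similar amounts at 1 week (1.63) and at 12 weeks (1.21). The covariate could thus move the difference of the diet effects only little, so it cannot decide on clock phase. Outside the Cyp4a and Acot families 10 of 19 members were called, against shared probes as the whole cause. Without mice 41 and 43 of the chow group, 15 of 17 stayed called. The length of feeding, age and any batch between the collection weeks that acted on 1 diet more than on the other may each contribute and were not tested.

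At 12 weeks of high-fat diet 11 of 19 male-biased genes were lower, and of 23 female-biased genes 8 rose, 2 fell and 13 did not pass (camera adjusted p = 0.000495, 0.229 with an estimated correlation). Xist and Ddx3y lay within 0.32 log2 units of their medians over all arrays (5.28 and 12.40) in that group, which argues against female livers among its arrays. Over all groups Xist lay at 5.06 to 5.51 and Ddx3y at 11.86 to 13.04, which argues against female livers in the other groups as well. Of the 8 that rose 6 lay outside the Cyp2b family, against its shared probes as the whole cause. The female-biased list shares 1 member each with the PPAR-alpha, fatty acid oxidation and lipid uptake lists, among them Cd36. Those lists rose as well, so the shared members are not separate evidence of a change in sex-biased genes. The female-biased list also shares 4 members with the xenobiotic metabolism list, and the male-biased list shares 2 with it. With the clock gene score as a covariate 19 of the 19 called in these directions, the 2 that fell left out, stayed called, with a median size of 1.66 before and 1.45 after. A change in the hormonal control of these genes by the diet may be one reason, and no hormone was measured.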

How the results depend on the processing

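The fits without mice 59 and 60, without mice 41 and 43 and with the clock gene score were chosen after seeing the data, the other alternatives before it. Of the results for named genes 1507 kept their direction and side of the threshold, 38 lost and 3 gained their call. For the described lists 282 kept it and 15 lost it, and no result reversed.

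Asking for a fold change of at least 1.5 in addition left, by construction, 376 genes at 1 week, 597 at 12 weeks, 504 for the difference of both diet effects, 140 over time on chow and 1120 on the high-fat diet. With an estimated correlation camera called 8 lists at 1 week, 4 at 12 weeks, 8 for the difference, 0 over time on chow and 10 on the high-fat diet, and fry called 11 at 12 weeks and 6 over time on chow. Without mice 59 and 60, 568 genes changed at 1 week, 514 of them shared. The groups of 12 weeks alone gave 1313 genes with fewer samples, and on chow all clusters gave 419 and the clock gene score 158. Apart from the lower sample numbers, the cause was not tested.

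With each mouse left out in turn, 625 (without mouse 6, chow, 1 week) to 1104 genes changed at 1 week, 1403 to 2265 at 12 weeks, 617 to 967 for the difference, 157 (without mouse 4, chow, 1 week) to 355 on chow and 3222 to 4027 on the high-fat diet. Lists ran from 20 to 23, 14 to 18, 21 to 22, 11 to 16 and 22 to 27 in that order. The correlation of both diet effects ran from 0.14 to 0.20, and over the other alternatives from 0.15 to 0.25. Centred medians moved the share of called genes that rose from 35% to 19.6% at 1 week and from 57.5% to 28.7% at 12 weeks, and a repeated quantile normalization from 76.5% to 63.2% for the difference and from 66.2% to 49.8% on the high-fat diet. The balance is not settled at 12 weeks and over time on the high-fat diet, but falls prevailed at 1 week and rises for the difference in every fit. Signal near the array background limits changes in dim genes. No paired analysis was possible because each mouse number occurs once.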

Other observations

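Gene ontology terms and the correlations across mice were tests chosen only after the results were seen, and the counts of other splits were chosen before them. The p values of the correlations do not account for the choice of their genes after the values had been seen. Genes of the tricarboxylic acid cycle were over-represented among those lower at 1 week of high-fat diet, with 9 of 29 (0.821 expected, adjusted p = 2.10e-05 by Fisher's exact test over 2335 terms). They were Aco1, Cs, Dlat, Dlst, Idh1, Idh2, Mdh1, Pdha1 and Sdhd, with log2 fold changes of -0.49 for Cs, -0.45 for Idh1 and -0.32 for Mdh1. From 1 to 12 weeks on the high-fat diet 16 of 29 were higher (2.52 expected, adjusted p = 1.28e-07). At 12 weeks of high-fat diet 7 of 20 genes of glycogen synthesis were higher (0.804 expected, adjusted p = 0.00143), among them Gbe1 at 0.75. Of the genes of peroxisome organization 7 of 20 were higher as well (adjusted p = 0.00143), among them Pex3, Pex16 and Pex19.

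Complement activation genes were lower at 12 weeks of high-fat diet in 5 of 15 cases (0.503 expected, adjusted p = 0.0107), which were C1ra, C1rb, C2, C8a and Hc. For 6 of 15 the diet effect was lower at 12 weeks than at 1 week (0.109 expected, adjusted p = 3.45e-07). The complement gene C6 rose by 1.29 at 1 week and fell by 1.09 at 12 weeks, C9 rose by 0.70 and fell by 0.82, and Hc rose by 0.43 and fell by 0.44. C6 is also in the male-biased list, so its fall is not separate evidence, and C1ra and C1rb are near-identical copies whose probes may be shared. Of the DNA methylation machinery list 3 of 17 fell at 12 weeks (camera adjusted p = 0.0408, 0.311 with an estimated correlation), which were Dnmt3a (-0.26, adjusted p = 0.0431), Tet3 (-0.35, adjusted p = 0.0245) and Mbd2 (-0.31, adjusted p = 0.0358). Dnmt1 had a log2 fold change of 0.00 (adjusted p = 0.998). Over time on chow 5 of 95 genes of extracellular matrix organization were lower (0.427 expected, adjusted p = 0.00844).

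The number of genes called in each comparison was set against 100 splits of the same arrays, the real one included. As many genes as the real count came from 1 split, the real one, in each of the 5 comparisons. Chance alone is thus unlikely for them, though 1 in 100 is the smallest share that these splits can show. The real and the highest other counts were 1042 and 168 at 1 week, 2005 and 341 at 12 weeks, 761 and 341 for the difference of both diet effects, 255 and 51 on chow, and 3789 and 1027 over time on the high-fat diet.

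For the number of lists called by camera, as many came from 4 splits at 1 week (21 real, 23 highest other). It was 4 for the difference (21 and 22) and 3 over time on the high-fat diet (24 and 25). These numbers were under the bound set beforehand, but in each another split called more lists than the real one. Chance is therefore not clearly excluded there. It cannot be excluded at 12 weeks, with 8 splits (17 and 19), nor over time on chow, with 10 (15 and 18). The other splits called a median of 8 to 13 lists, so camera with its preset correlation called many lists whatever the grouping. For the correlation of both diet effects 14 permutations gave one as large (0.17 real, 0.29 highest other), so chance cannot be excluded.

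Mice on the high-fat diet for 12 weeks differed widely in Hsd3b5. A hypothesis is that the male-biased and female-biased programmes moved together within mice, so that mice with higher Cyp2b9 may have lower Hsd3b5. Over these 8 mice Pearson's r was -0.80 (two-sided exact permutation p = 0.0150, adjusted 0.0150 over 2 relations) and Spearman's rho was -0.83 (exact permutation p = 0.0154, adjusted 0.0154). Without the 2 mice farthest from the median of Cyp2b9 r was -0.95. In the other groups r was -0.63 and -0.29 on chow at 1 and 12 weeks and -0.02 on the high-fat diet at 1 week (adjusted p = 0.299, 0.779 and 0.969 over 6 relations).

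Within the high-fat group of 1 week, mice with higher Saa2 may have lower Dbp, a clock output gene. Over these 8 mice Pearson's r was -0.95 (two-sided exact permutation p = 0.000198, adjusted 0.000397 over 2 relations) and Spearman's rho was -0.95 (exact permutation p = 0.00114, adjusted 0.00228). Without the 2 mice farthest from the median of Saa2 r was -0.96. In the other groups the relation did not pass and its sign varied, with r of 0.64 and -0.59 on chow at 1 and 12 weeks and -0.13 on the high-fat diet at 12 weeks (adjusted p = 0.299, 0.299 and 0.957 over 6 relations). The time of day of sampling is not known, so an acute phase response that lowered Dbp and a shared effect of the hour of sampling both remain open.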
